A study of Homo sapiens with 4 samples.

How the data were processed

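The series holds ribosome-protected fragments of 4 PANC-1 libraries, 2 from negative control cells and 2 from FBXO32-depleted cells. Per the labels' protocols, cells were treated with 100 μg/mL cycloheximide for 2 min to hold ribosomes in place, lysates were digested with RNase I and DNase I for 45 min, fragments longer than 17 nt were recovered through size-exclusion columns, ribosomal RNA was removed and small RNA libraries were made. No RNA-seq of the same cells was used here, so footprint levels, not translational efficiencies, were compared, and a change in footprint level can come from the mRNA level or from its translation. The submitters' processing notes name fastp, Bowtie2 2.2.8, STAR, RSEM, DESeq2 and the build GRCh38, with no order or role. The annotation release, the length definition, the reads counted (coding sequence or whole transcript) and any filter are not given in the sources used here.

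The deposited table gives 1 TPM value per gene and library for 20307 Ensembl genes. Per the file headers the unit is TPM, and each column sums to 1000000. TPM is scaled by a gene's length, is relative within a library and keeps no depth, so a gene's TPM falls when others rise. Of the genes, 5227 were listed at 0 in all libraries. A listed 0 can be a failed estimate, so no fold is given against a group at 0. The columns are named KO and NS with a number. KO was read as FBXO32-depleted, NS, the only other arm, as the negative control, and the number as the bioreplicate number of the titles. This reading rests on the column names alone. FBXO32 was lower in the columns read as depleted but did not pass the test (limma adjusted p = 0.429), so the values do not settle this reading. Symbols were taken from a gene name table by Ensembl identifier, and 19702 genes had one. Gene positions and coding lengths come from GENCODE release 29 on GRCh38, whose release need not be the one used for the table. The coding length is that of the longest annotated coding sequence of a gene.

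The planned count test was not used because the table holds no counts. Instead, as laid down before the data were examined for a normalized unit, log2(TPM + 1) was tested with limma 3.58.1 in R 4.3.3, with trend and robust variance moderation, on 11623 genes with at least 1 TPM in at least 2 libraries. All 4 libraries entered the fit without covariates. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. With 2 residual degrees of freedom the moderation gave most genes the pooled spread alone (infinite prior degrees of freedom), so a gene's own replicate spread had little part in its p-value. Errors are SD over 2 libraries for TPM and SE from limma for log2 fold changes.

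Before the data were examined, 37 gene lists were fixed, of which 29 had at least 5 tested members. Each was tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With 2 residual degrees of freedom an estimated correlation is poorly determined, and under it no list had an unadjusted p under 0.05. Every list then had a camera adjusted p between 0.927 and 0.97, so this setting does not tell the lists apart. A list of ribosomal and small noncoding RNAs had no genes in the table, and the 8 lists of other cell types are reported by counts. Of the lists tested, 1 is not reported here, nor is 1 of the genes looked at after the values were seen. The genes named are FBXO32, ITGB1 and EEF1A1, then the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 TPM, a symbol and groups that do not overlap, then up to 3 members with the smallest p of each list that passed or held a call. Other called members of a list with 5 or fewer calls in a direction are named too, chosen after their values were seen. ITGB1 and EEF1A1 were fixed from recollection of the published study, which was not read here.

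Data were simulated with the real means and the moderated spread of the 11623 genes, drawn independently for each gene and library. The fit called 83 of 100 genes changed by 2 on the log2 scale and 15 of 100 changed by 1. It also called 9 of 11423 unchanged genes, and camera gave an unadjusted p under 0.05 to 2 of 100 random lists. The simulation held no correlation between genes and no trend with coding length. It therefore cannot give the rate of false calls in the real libraries. A simulated gene that changed by 1 on the log2 scale was usually missed, and a gene not past the threshold is not shown to be unchanged.

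The alternatives fixed beforehand were median-ratio scaling, no filter on low values, a minimum of 5 TPM, limma without trend or without robust moderation, a pseudocount of 0.1, the replicate number as a block, removal of the 20 most abundant and the mitochondrial genes, other thresholds and leaving out each library. Removal of each library's trend with coding length, by a natural spline with 4 degrees of freedom fitted to deviations from the gene means, was added after seeing the data. This removal also takes out any part of the trend that is due to depletion, and it raises long genes and lowers short ones in the comparison. Genes without an annotated coding length were left out of it. The labels give no sequencing batch or date. Figures were drawn with matplotlib 3.10.9.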

Results

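Ribosome footprints were profiled in PANC-1 cells, an established human pancreatic ductal adenocarcinoma line, in which FBXO32 had been depleted or which served as negative controls. FBXO32, also called atrogin-1, is an F-box protein, the substrate-binding part of an SCF ubiquitin ligase. The question asked here was which genes differ in footprint level between these groups. Footprints alone cannot tell a change in translation from one in mRNA level. There were 4 libraries, 2 per group, each holding fragments protected by ribosomes after cycloheximide arrest, and each gene had 1 TPM value (a length-scaled share of the library) per library. TPM values carry no read depth, so the depth behind each value is unknown and no counting interval can be given. Between 13307 and 13805 of the 20307 listed genes were above 0 in a library, and 11623 reached 1 TPM in at least 2 libraries and were tested. The labels call the 2 libraries of a group bioreplicates without saying how the cultures were separated. The p-values rest on a spread between these libraries pooled over genes, in which a gene's own replicate spread had little part. They do not measure the spread between cultures known to be independent.

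FBXO32 itself was not past the test in the depleted libraries, ITGB1 was higher, and EEF1A1 showed no consistent difference. FBXO32 (ENSG00000156804, GRCh38 chromosome 8, 123497889 to 123541206, minus strand) had 18.1 and 21.6 TPM in the negative controls and 14.3 and 12.9 TPM in the depleted libraries. Both depleted values lay below both control values, but the log2 fold change of -0.51 ± 0.45 (SE) did not pass the test (limma adjusted p = 0.429), and its 95% confidence interval ran from -1.40 to 0.38. The depletion is therefore known from the labels alone, and here depletion and depleted name the group as labelled. ITGB1, the integrin beta 1 subunit of matrix receptors (ENSG00000150093, chromosome 10, 32900319 to 33005792, minus strand), rose from 730.3 ± 316 to 1326 ± 143 TPM (SD, n = 2), a log2 fold change of 0.93 ± 0.36 (limma adjusted p = 0.0411). ITGB1 and EEF1A1 were fixed from recollection of the published study, which was not read here, and if that study chose ITGB1 on these libraries its call is not independent evidence. The log2 fold change of ITGB1 was 1.62 with the coding-length trend removed (limma adjusted p = 0.00176), a setting that takes no part of the trend to be due to depletion. The ITGB1 call ended without negative control replicate 1 (log2 fold change 0.47, limma adjusted p = 0.594), without either depleted replicate (0.0703 and 0.243) and with the replicate number as a block (0.06). EEF1A1, the elongation factor that delivers aminoacyl-tRNA to the ribosome (ENSG00000156508, chromosome 6, 73515750 to 73523797, minus strand), had 3261 and 4874 TPM in the controls and 5495 and 1829 TPM in the depleted libraries. Its log2 fold change was -0.33 ± 0.34 (limma adjusted p = 0.504), and it turned to 0.46 without depleted replicate 2.

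**Figure D1:**
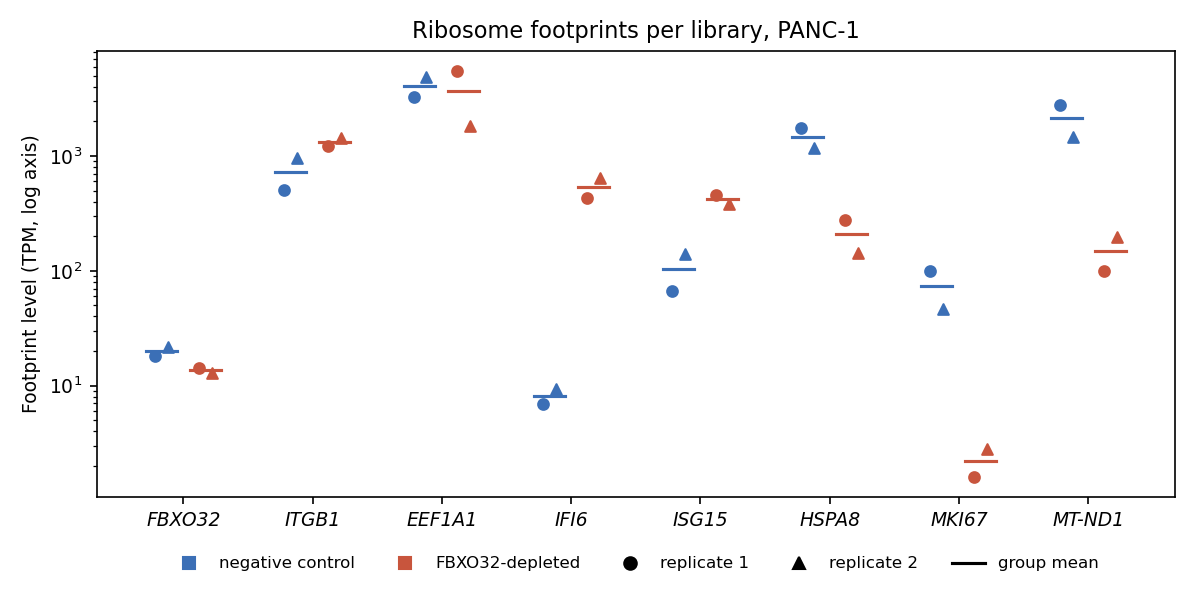
Footprint level in TPM (log axis) of 8 genes in each of the 4 PANC-1 libraries, with negative controls in blue, FBXO32-depleted libraries in red, replicates 1 and 2 as circles and triangles, and group means as bars. FBXO32 lay between 12.9 and 21.6 TPM in all 4 libraries, with both depleted values below both control values. IFI6, ISG15, HSPA8, MKI67 and MT-ND1 separated the groups more widely.

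Footprints of 2990 of the 11623 tested genes differed between the groups, of which 722 were higher and 2268 lower after FBXO32 depletion (limma, Benjamini-Hochberg adjusted p under 0.05). On the log2(TPM + 1) scale, the largest rise among the genes named was that of IFI6, an interferon-induced mitochondrial protein. IFI6 (ENSG00000126709, chromosome 1, 27666061 to 27672218, minus strand) went from 8.12 ± 1.73 to 538.1 ± 155 TPM (SD, n = 2). Its log2 fold change was 5.87 ± 0.41 (SE), or 58.4-fold (limma adjusted p = 3.72e-43). IFI6 had the same fold change and still passed without the filter on low values, but its adjusted p was many orders of magnitude larger. The size of p-values this small therefore depends on the settings of the fit and does not measure certainty about a gene. IFI27, another interferon-induced gene, went from 2.27 TPM and a listed 0 in the controls to 30.7 and 29.2 TPM. CCL5, a chemokine, rose from 2.24 ± 2.32 to 22.2 ± 8.98 TPM, and S100P, a calcium-binding protein, from 3.07 ± 1.33 to 29.8 ± 8.54 TPM. The CCL5 call ended without negative control replicate 1 (limma adjusted p = 0.0518). AQP3, a water and glycerol channel, and ORAI3, a calcium channel subunit, rose by 2.65 ± 0.48 and 2.64 ± 0.48. The largest fall among the genes named was that of MKI67, the Ki-67 proliferation marker, from 73.1 ± 38.2 to 2.22 ± 0.85 TPM. Its log2 fold change was -4.45 ± 0.46 (limma adjusted p = 2.37e-19). The MKI67 fold change was also unchanged and past the threshold without the filter on low values, with an adjusted p many orders of magnitude larger. The log2 fold change was -4.28 ± 0.42 for SMTN, the actin-binding smoothelin, -4.04 ± 0.46 for the centrosomal gene CEP250 and -3.84 ± 0.45 for the cytokinesis kinase gene CIT. FBXW7, which like FBXO32 encodes an F-box protein, fell from 87.9 ± 52.5 to 4.54 ± 0.57 TPM.

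Several of the largest changes lie in genes that share sequence with others, and their values are uncertain where the counting split reads. CHURC1-FNTB, a read-through gene over CHURC1 and FNTB, had 1.89 TPM and a listed 0 in the controls and 58.6 and 98.0 TPM in the depleted libraries. EIF4A1, which overlaps the read-through gene SENP3-EIF4A1, fell from 106.1 ± 49.6 to 5.60 ± 1.82 TPM. RAMAC, a cofactor of mRNA cap methylation, was listed at 0 in both controls and at 19.9 and 51.0 TPM after depletion. The immunoglobulin kappa segments IGKJ3 (15.6 and 16.9 TPM) and IGKC (19.6 and 11.04 TPM) were listed at 0 in both depleted libraries. IGKJ3 has a coding length of 38 nt, and as TPM is scaled by length its values could rest on few reads. With a pseudocount of 0.1 the calls of IFI27 and CHURC1-FNTB ended (limma adjusted p = 0.192 and 0.14), and each had 1 control library listed at 0.

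The count of changed genes depended strongly on which library was left out. Such a fit has 1 library in a group and can have less power. A call that ended in it is therefore not shown to have lost its effect. Of 3035 genes without depleted replicate 1, 2467 were among the 2990, and the count was 384 without negative control replicate 1, 1807 without negative control replicate 2 and 1495 without depleted replicate 2. Scaling the libraries by median ratios raised the median log2 fold change of all genes from -0.16 to 0.02, and the calls were then 1251 higher and 1904 lower. Across genes, the Pearson correlation of log2(TPM + 1) was 0.958 between the controls and 0.961 between the depleted libraries. It was 0.921 between negative control replicate 2 and depleted replicate 1, and 0.835 between negative control replicate 1 and depleted replicate 2.

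Interferon-stimulated genes were higher in the depleted libraries. Of the 20 tested members of the list, 5 rose, 0 fell and 15 did not pass. Where a list holds 5 or fewer calls in a direction, members outside the rule for named genes are also named, and those were chosen after their values were seen. Besides IFI6 and IFI27, ISG15, a ubiquitin-like modifier, rose from 102.7 ± 51.6 to 419.6 ± 51.6 TPM (SD, n = 2), a log2 fold change of 2.11 ± 0.38 (limma adjusted p = 1.13e-06). OASL, an antiviral synthetase-like protein, rose from 0.335 ± 0.0177 to 2.63 ± 0.32 TPM, and IFI35 from 4.61 ± 0.457 to 12.4 ± 1.76 TPM. When adjusted over the list alone, 6 rose. The list passed camera's test with its preset correlation (adjusted p = 2.36e-06), with a median log2 fold change of 0.68. With the correlation estimated from the data it did not pass (camera adjusted p = 0.927), and neither did any other list. The number that rose was 2 without negative control replicate 1 and 3 without any other single library, and 1 member fell without depleted replicate 1. It was 9 with the coding-length trend removed. ISG15 was among those lost without negative control replicate 1, where its log2 fold change was 1.58.

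Cell-cycle genes were lower in the depleted libraries in both lists. Of 31 tested G2 and M phase genes, 19 fell, 0 rose and 12 did not pass, and the median log2 fold change was -1.34 (camera adjusted p = 1.94e-08). MKI67 was joined by KIF20A, a mitotic kinesin (-3.67 ± 0.42), and TPX2, a spindle assembly factor, which fell from 260.3 ± 67.7 to 21.5 ± 3.63 TPM. Of 28 S phase and DNA replication genes, 16 fell, 0 rose and 12 did not pass, with a median of -1.27 (camera adjusted p = 2.36e-06). The log2 fold change was -3.42 ± 0.48 for POLA1, the catalytic subunit of DNA polymerase alpha, -2.92 ± 0.45 for POLE, that of DNA polymerase epsilon, and -2.78 ± 0.42 for the replicative helicase subunit gene MCM3. When adjusted over the list alone, 21 G2 and M phase and 17 S phase genes fell. With an estimated correlation neither list passed, like every other list tested (both camera adjusted p = 0.927). The numbers that fell were 5 G2 and M phase and 6 S phase genes without negative control replicate 1. S phase calls also dropped to 9 without negative control replicate 2 or the filter on low values, and to 8 without depleted replicate 2. With the coding-length trend removed, 12 and 11 fell, and both lists still passed camera (adjusted p = 2.53e-07 and 2.92e-07). Of 34 replication-dependent histone genes, 3 fell, 0 rose and 31 did not pass, with a median of -0.16. H2BC5, whose near-identical copies could share its reads, fell from 1177 ± 298 to 214.4 ± 35.3 TPM, and the linker histone genes H1-5 and H1-4 had log2 fold changes of -1.62 ± 0.38 and -1.42 ± 0.38. The histone list did not pass camera (adjusted p = 0.675) and passed downward with the coding-length trend removed (6.16e-07), where 9 fell. Leaving out negative control replicate 1 left 1 histone gene that fell, with the calls of H1-5 and H1-4 ended (limma adjusted p = 0.119 and 0.171), and leaving out depleted replicate 2 ended that of H1-4 (0.0526). In all, 3 members fell when adjusted over the list alone.

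Parts of the translation machinery were lower, while most ribosomal protein genes did not pass the test. Of 37 initiation factor genes, 17 fell, 1 rose and 19 did not pass, with a median log2 fold change of -0.79 (camera adjusted p = 4.52e-05). EIF4G1, the scaffold of the cap-binding complex, fell from 229.0 ± 90.6 to 22.0 ± 4.19 TPM, and EIF3C, a subunit of the eIF3 complex with a near-identical copy, from 463.9 ± 136 to 61.6 ± 21.3 TPM. Of 22 cytosolic aminoacyl-tRNA synthetase genes, 11 fell, 0 rose and 11 did not pass, with a median of -1.02 (camera adjusted p = 4.72e-05). NARS1, TARS1 and QARS1, the asparaginyl-, threonyl- and glutaminyl-tRNA synthetases, had log2 fold changes of -2.70, -2.64 and -2.26. EIF1, a start-codon selection factor, was the initiation factor gene that rose, from 993.5 ± 179 to 2040 ± 426 TPM. Counted as adjusted over the list alone, 17 initiation factor genes fell and 2 rose, and 11 synthetase genes fell. Like every other list, neither passed with an estimated correlation (both camera adjusted p = 0.927). Leaving out negative control replicate 1 gave 6 initiation factor and 2 synthetase genes that fell. Synthetase calls numbered 6 without negative control replicate 2 or the filter on low values, 17 without depleted replicate 1 and 5 without depleted replicate 2. With the coding-length trend removed, 16 and 5 fell, and both lists still passed camera (adjusted p = 3.76e-06 and 0.00126).

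Of 16 elongation factor genes, 2 fell, 0 rose and 14 did not pass (camera adjusted p = 0.91), and the list's direction flipped under median-ratio scaling. EEF2, the translocation factor, fell from 411.0 ± 64.6 to 109.4 ± 42.6 TPM (log2 fold change -1.95 ± 0.38, limma adjusted p = 8.44e-06). EEF1A2, the paralog of EEF1A1, fell by 0.99 on the log2 scale (limma adjusted p = 0.0446), a call that ended in several settings, among them median-ratio scaling (0.14). By p-values adjusted over the list alone, 1 elongation factor gene fell. The number that fell was 0 without negative control replicate 1, where the EEF2 call ended (limma adjusted p = 0.0646), 6 without depleted replicate 1 and 1 without either other library. It was 1, with 1 rise, under median-ratio scaling and with the coding-length trend removed. Of 78 cytosolic ribosomal protein genes, 4 rose, 7 fell and 67 did not pass, with a median of 0.13 (camera adjusted p = 0.172). RPS25 fell from 7791 ± 2783 to 2706 ± 98.3 TPM, while the falls of RPL41 (-2.07 ± 0.41) and RPL23A (-2.11 ± 0.48) are uncertain because processed copies of these genes could share their reads. RPS28 (log2 fold change 1.54 ± 0.36), RPL39 (1.02 ± 0.35), RPL35A (0.95 ± 0.35) and RPS29 (0.89 ± 0.35) rose. Counts adjusted over the list alone were 3 rises and 7 falls. The numbers of rises and falls were 0 and 0 without negative control replicate 1, 1 and 5 without negative control replicate 2, and 0 and 5 without depleted replicate 2. Median-ratio scaling gave 6 rises and 5 falls. The ribosomal protein list turned downward with the coding-length trend removed (camera adjusted p = 0.00339), with 1 rise and 12 falls.

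Mitochondrially encoded genes were lower in the depleted libraries. Of 13, 12 fell and 1, MT-ATP8, rose, with a median log2 fold change of -3.13 (camera adjusted p = 6.81e-23). The counts were unchanged when adjusted over the list alone. The log2 fold changes of MT-ND1 and MT-ND3, complex I subunits, were -3.84 ± 0.37 and -3.99 ± 0.38, and MT-CO2, a complex IV subunit, fell from 6937 ± 2165 to 740.7 ± 314 TPM (SD, n = 2). MT-ATP8 overlaps MT-ATP6, so its value is uncertain. Its call ended with the coding-length trend removed (limma adjusted p = 0.283), and 0 mitochondrially encoded genes rose without any 1 library except depleted replicate 1, with the replicate block, without the filter on low values, without the variance trend or without robust moderation. Together these genes took 3.21% and 1.92% of the TPM in the controls and 0.364% and 0.694% in the depleted libraries. Like every other list, this list did not pass with an estimated correlation (camera adjusted p = 0.927). The number that fell was 10 without negative control replicate 1 and 12 without any other single library.

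Of 55 nuclear-encoded subunits of oxidative phosphorylation, 16 rose, 1 fell and 38 did not pass, with a median log2 fold change of 0.53 (camera adjusted p = 2.32e-05). NDUFA1, a complex I subunit, rose from 1800 ± 383 to 4552 ± 1424 TPM, and the complex IV subunit genes COX6B1 and COX6C rose by 1.26 ± 0.35 and 1.24 ± 0.36 on the log2 scale. UQCRQ, a complex III subunit, fell from 1496 ± 484 to 773.2 ± 199 TPM. The counts were the same adjusted over the list alone. The median coding length of this list was 486 nt, and with the coding-length trend removed, 4 rose, 2 fell and the list no longer passed (camera adjusted p = 0.0925). Like every other list, it did not pass with an estimated correlation (camera adjusted p = 0.927). Fewer members rose without negative control replicate 1, negative control replicate 2 or depleted replicate 2. Without depleted replicate 1, 14 rose and 6 fell. Only 2 rose when low values were not filtered.

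Cytosolic heat shock genes were lower in the depleted libraries. Of 14 tested, 12 fell, 0 rose and 2 did not pass, with a median log2 fold change of -1.41 (camera adjusted p = 3.51e-05). HSPA8, the constitutive Hsc70 chaperone, fell from 1463 ± 408 to 210.2 ± 97.0 TPM and HSP90AA1, an inducible Hsp90, from 634.1 ± 126 to 137.9 ± 67.9 TPM. HSPA1B, which is near-identical to HSPA1A, had a log2 fold change of -2.64 ± 0.46. The number that fell was also 12 adjusted over the list alone. With an estimated correlation the list did not pass, like every other list (camera adjusted p = 0.927). Without negative control replicate 1, 3 fell, 5 fell without negative control replicate 2 or depleted replicate 2, and 4 fell without the filter on low values. With the coding-length trend removed, 7 did, and the list still passed camera (adjusted p = 2.32e-05). Among 25 endoplasmic reticulum chaperone and unfolded protein response genes, HSP90B1 fell (-0.92 ± 0.36, limma adjusted p = 0.0469), 0 rose and 24 did not pass (camera adjusted p = 0.291). The HSP90B1 call ended without the filter on low values (limma adjusted p = 0.102), without the variance trend (0.11), without robust moderation (0.0519) and with the replicate block (0.0599). It also ended with median-ratio scaling (limma adjusted p = 0.188) and with the coding-length trend removed (-0.22, limma adjusted p = 0.594). In these last settings 1 and 3 members of the list rose and 0 fell. No member changed when adjusted over the list alone (limma), and at an unadjusted p under 0.05, 1 was higher and 2 were lower. Of 28 ATF4 and amino acid response genes, 4 fell, 0 rose and 24 did not pass (camera adjusted p = 0.675). Among them were PPP1R15A, a phosphatase subunit acting on eIF2 (-2.24 ± 0.44), and DDIT3, the transcription factor CHOP (-1.91 ± 0.43), besides the serine and one-carbon enzymes PHGDH (-1.41 ± 0.44) and SHMT2 (-1.09 ± 0.42), and 3 fell when adjusted over the list alone. Without negative control replicate 1 the calls of PPP1R15A, DDIT3 and PHGDH ended, at log2 fold changes of -1.95, -1.65 and -1.14. The number that fell in the ATF4 list varied with the library left out, and it was 2 with the coding-length trend removed.

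Of 11 tested integrin genes, 2 rose, 1 fell and 8 did not pass, with a median log2 fold change of 0.55 (camera adjusted p = 0.319). ITGA5, the partner of ITGB1 in the fibronectin receptor, rose from 35.3 ± 5.14 to 80.7 ± 8.96 TPM (limma adjusted p = 0.0229). The ITGA5 call ended without the filter on low values (limma adjusted p = 0.07). ITGB5 fell from 77.8 ± 6.75 to 22.2 ± 8.64 TPM (limma adjusted p = 0.000246). The counts were the same adjusted over the list alone. With negative control replicate 1 left out, 0 integrin genes changed (limma). With the coding-length trend removed, 7 rose, 1 fell and the integrin list passed (camera adjusted p = 0.00126). The removal raises long genes, and the median coding length of this list was 3147 nt. This pass, and that of the extracellular matrix list in the same setting, takes no part of the trend to be due to depletion. Of 23 focal adhesion genes, 7 fell, 0 rose and 16 did not pass, with a median of -0.56 (camera adjusted p = 0.00937). The log2 fold changes of the actin crosslinkers ACTN4, ACTN1 and FLNA were -2.66, -2.77 and -2.58. Of this list 8 fell when adjusted over the list alone. The focal adhesion list was lost with the coding-length trend removed (camera adjusted p = 0.17) and did not pass without depleted replicate 2. With an estimated correlation it did not pass, like every other list (camera adjusted p = 0.927). Leaving out negative control replicate 1 gave 3 that fell. Of 30 extracellular matrix genes, 0 changed in the limma fit or adjusted over the list alone, with 5 higher and 2 lower at an unadjusted p under 0.05, and the median was 0.22 (camera adjusted p = 0.0683). With the coding-length trend removed, 11 rose and the list passed upward (camera adjusted p = 2.32e-05), and with median-ratio scaling 5 rose. It also passed upward without depleted replicate 1 (camera adjusted p = 0.0391).

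Epithelial and mesenchymal markers held calls in both directions, and neither list passed camera (adjusted p = 0.665 and 0.441). Of 18 epithelial genes, 5 fell, 1 rose and 12 did not pass, a balance that turned to 4 falls and 4 rises with median-ratio scaling and to 1 fall and 3 rises with the coding-length trend removed, and of 14 mesenchymal genes, 7 fell, 2 rose and 5 did not pass, against 4 falls and 3 rises and 2 falls and 1 rise in those settings. Counts adjusted over the list alone were 5 falls and 2 rises among epithelial and 7 falls and 3 rises among mesenchymal genes. With no filter on low values, 2 epithelial and 3 mesenchymal genes fell and 0 rose. The epithelial list had a median log2 fold change of -0.12 and a mean of -0.06, although camera's direction was upward, and the mesenchymal median was -0.93. The simple epithelial keratin genes KRT8 (-1.27 ± 0.38) and KRT18 (-0.93 ± 0.36) and the junction gene JUP (-1.27 ± 0.43) fell. The KRT8 call ended without the filter on low values (limma adjusted p = 0.123). Its log2 fold change was -0.51 without depleted replicate 2. The groups overlapped for JUP, with 34.5 and 164 TPM in the controls and 52.98 and 17.8 TPM in the depleted libraries. CLDN3, a tight junction claudin, rose from 0.841 ± 0.746 to 3.73 ± 0.912 TPM. MSN, which links membrane and actin, fell from 127.3 ± 4.83 to 20.9 ± 4.26 TPM, and the repressor gene ZEB1 from 10.8 ± 2.36 to 2.61 ± 1.11 TPM, while S100A4 rose from 849.6 ± 232 to 1798 ± 216 TPM and TWIST2 by a log2 fold change of 1.39 ± 0.46. Without negative control replicate 1, 1 epithelial and 1 mesenchymal gene fell and 0 rose. The falls of ZEB1 and of the junction genes DSP and TJP1 did not pass with the coding-length trend removed (limma adjusted p = 0.137, 0.274 and 0.226). In that setting KRT18 (0.121), JUP (0.757), CLDN3 (0.0531), S100A4 (0.0825) and TWIST2 (0.102) did not pass either.

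**Figure D2:**
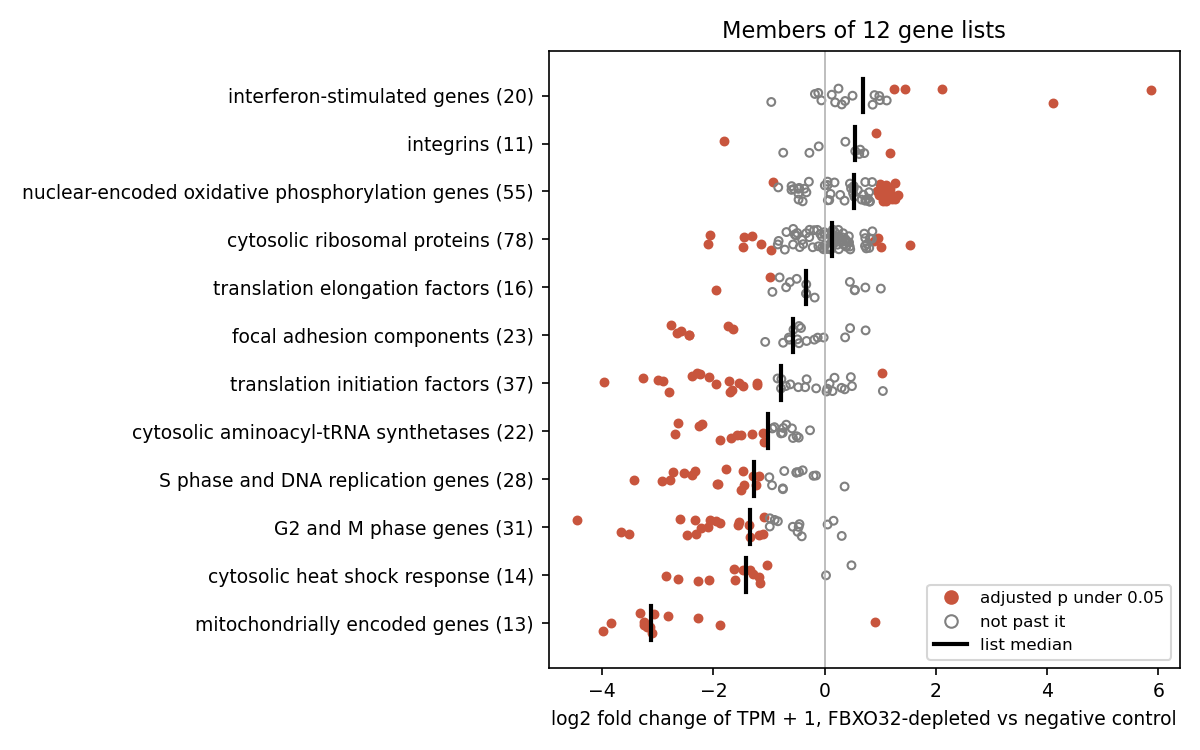
Log2 fold change of TPM + 1 (x axis, FBXO32-depleted against negative control) of each tested member of 12 gene lists, with filled points past an adjusted p under 0.05, open points not past it, black bars for list medians and the number of tested members in brackets. Medians ran from -3.13 for mitochondrially encoded genes to 0.68 for interferon-stimulated genes.

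Signalling and metabolic lists held few calls, and none of the following passed camera with all libraries and no correction for length. The proteasome list passed downward with the coding-length trend removed (camera adjusted p = 0.0259) and without depleted replicate 1 (0.00716), and the glycolysis list without depleted replicate 1 (0.0225). In the NF-kB and inflammatory list 2 of 18 rose and 4 fell. The chemokine gene CCL20 rose from 3.52 ± 2.54 to 17.4 ± 1.16 TPM, and CXCL1, another chemokine, from 16.3 ± 3.11 to 49.2 ± 16.5 TPM. The inhibitor gene NFKBIA (-1.33 ± 0.39), NFKB2 (-1.47 ± 0.46), BIRC3 (-1.89 ± 0.47) and TNFAIP2 (-1.70 ± 0.39) fell. Of 20 p53 target genes 2 rose and 4 fell, with CDKN1A, the cyclin-dependent kinase inhibitor p21 (1.07 ± 0.39), and ZMAT3 (1.23 ± 0.46) rising and PLK3 (-2.75 ± 0.45), PLK2 (-1.22 ± 0.46), XPC (-1.69 ± 0.48) and GADD45A (-1.16 ± 0.40) falling. Median-ratio scaling gave 2 rises and 2 falls of p53 targets, and removal of the coding-length trend 1 and 2, where the calls of CDKN1A (limma adjusted p = 0.109), XPC (0.131) and PLK2 (0.26) ended. In the glycolysis and hypoxia list 7 of 31 fell and 1 rose. The glucose transporter gene SLC2A3 rose from 0.553 ± 0.782 to 2.22 ± 0.366 TPM, and PFKP, a phosphofructokinase, fell from 240.5 ± 17.7 to 74.4 ± 49.2 TPM. Among cholesterol and fatty acid synthesis genes 4 of 30 fell, namely FASN, ACLY, MVD and NSDHL, and the fall of FASN, the fatty acid synthase (-1.48 ± 0.40), and that of ACLY (-1.40 ± 0.43) did not pass with the coding-length trend removed (limma adjusted p = 0.466 and 0.312), where 4 genes of the list rose and 2 fell. Of 32 proteasome subunit genes 5 fell, PSMC3 from 502.9 ± 275 to 82.8 ± 40.8 TPM and PSMC4, PSMD4, PSMD6 and PSMC2 by smaller amounts, at most a log2 fold change of -1.14 ± 0.38 for PSMD4. With median-ratio scaling 1 proteasome gene fell, and the calls of PSMC4 and PSMD4 ended (limma adjusted p = 0.103 and 0.0711). Of 24 AKT and mTOR pathway genes 4 fell, namely the phosphoinositide 3-kinase subunit genes PIK3R2 (-1.75 ± 0.43) and PIK3R1 (-1.54 ± 0.48), RPTOR (-1.56 ± 0.47) and AKT2 (-1.13 ± 0.36). The calls of RPTOR and PIK3R1 ended with the coding-length trend removed (limma adjusted p = 0.293 and 0.14), where 2 of the list fell. In the SCF ligase and neddylation list, FBXW7 and the scaffold gene CUL1 (-1.18 ± 0.46, limma adjusted p = 0.0407) were the 2 of 21 that fell. Median-ratio scaling gave 2 rises and 1 fall in this list, and removal of the coding-length trend 2 and 2. The CUL1 call ended in both (limma adjusted p = 0.0723 and 0.372). In the YAP and TEAD list AMOTL1 (-2.05 ± 0.47) was the 1 of 15 that fell. In the list of FOXO and muscle atrophy genes 0 of 13 changed (limma), with 1 lower at an unadjusted p under 0.05. Calls adjusted over the list alone were 2 rises and 4 falls for the NF-kB list, 2 and 4 for p53 targets, 1 and 8 for glycolysis, and 0 rises with 4, 4, 4, 1, 1 and 0 falls for the lipid, proteasome, AKT, SCF, YAP and FOXO lists in turn. Camera's adjusted p lay between 0.423 and 0.955 for these lists. Camera's direction was upward against a negative mean in the NF-kB, p53, lipid, SCF, YAP and FOXO lists, and the median was negative too for NF-kB genes (-0.06) and p53 targets (-0.16). Without negative control replicate 1, 0 genes of these lists changed (limma) except 1 SCF gene that fell. Without depleted replicate 1, 15 glycolysis and 11 proteasome genes fell, and without depleted replicate 2, 0 and 1 did. Without negative control replicate 2, 1 glycolysis, 1 proteasome, 2 p53, 2 AKT and 2 lipid genes fell, and without the filter on low values 1 of each did. Median-ratio scaling gave 4 rises and 4 falls in the NF-kB list and 4 falls in the glycolysis list, and removal of the coding-length trend 3 falls in the latter.

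Markers of other cell types were mostly below the tested range. No erythroid or pancreatic acinar marker was tested, and the highest of them, HBB and REG1A, stayed at or under 0.858 and 0.319 TPM. The highest endothelial, endocrine and hepatocyte markers were ESAM, CHGB and SERPINA1, at up to 2.90, 3.05 and 2.75 TPM, and no tested gene of these lists changed (limma). Of 3 tested leukocyte markers 1, LYZ, fell (-2.35 ± 0.46), from 8.52 and 3.47 TPM to 0.632 TPM and a listed 0. Of 3 tested fibroblast markers 1, COL3A1, rose (1.22 ± 0.44) and 1, COL1A1, fell (-1.37 ± 0.41), the latter the highest of the list, at 111 and 86.5 TPM in the controls and 35.3 and 39.0 TPM after depletion. Of 5 tested neuronal markers 1, MAP2, fell (-2.59 ± 0.46), 2 fell when adjusted over the list alone, the list did not pass camera (adjusted p = 0.675), and TUBB3, which many carcinoma lines express, had 47.8 to 164 TPM.

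The change after depletion ran with coding length. Over 11525 tested genes with an annotated coding sequence, the median log2 fold change went from 0.54 in the eighth with the shortest sequences (up to 585 nt) to -0.90 in the eighth with the longest (3108 nt or more). Of 1445 genes in the shortest eighth, 308 rose and 94 fell, and of 1440 in the longest, 15 rose and 594 fell. Spearman's correlation of coding length with the log2 fold change was -0.456 across genes, which are not independent replicates. The difference of negative control replicate 2 minus 1 showed a correlation of -0.345, and that of depleted replicate 2 minus 1 showed -0.215. The TPM-weighted median coding length was 747 and 678 nt in the controls and 597 and 498 nt in the depleted libraries. With the coding-length trend removed from each library, 2500 genes changed, 1078 higher and 1422 lower, of which 1719 were among the 2990.

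**Figure D3:**
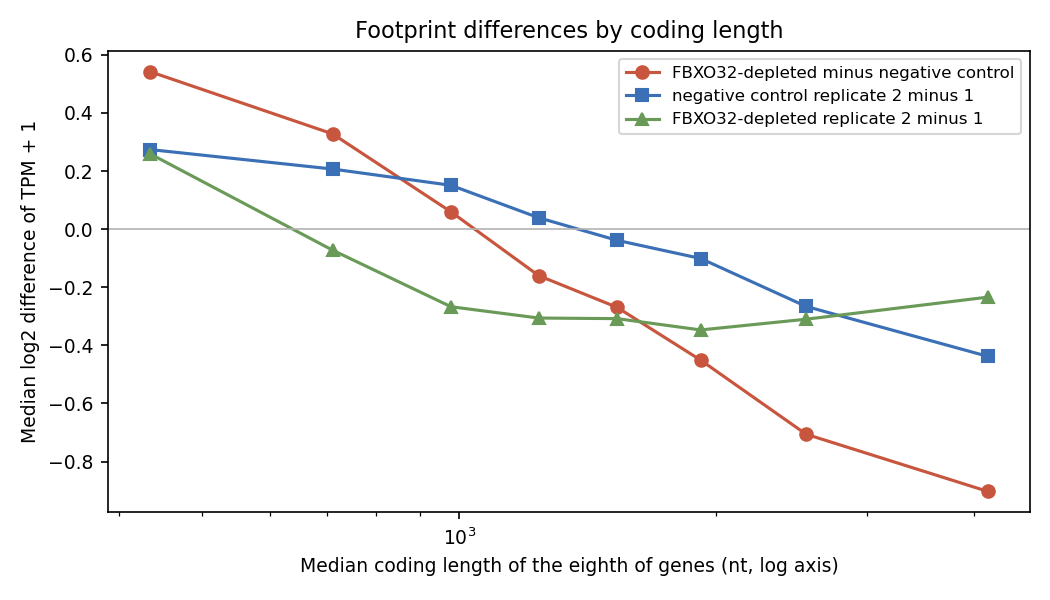
Median log2 difference of TPM + 1 (y axis) in 8 groups of genes ordered by coding length (x axis, median in nt, log axis), between depleted and control libraries (red circles) and between the replicates of each group (blue squares and green triangles). The difference between groups fell from 0.54 to -0.90, and that between the controls from 0.27 to -0.44.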

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

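The alternative that removes the coding-length trend was chosen after seeing the data. The counts of 2990 changed, 722 higher and 2268 lower genes moved without a filter on low values to 1529, 207 and 1322, where 15080 genes were tested. Median-ratio scaling gave 1251 higher genes, and removing the coding-length trend 1422 lower genes. Leaving out 1 library at a time gave 384 to 3035 changed, 37 to 646 higher and 347 to 2389 lower genes, with a lone library assumed to vary like the others. The lowest values came without negative control replicate 1, and the count fell to 1495 without depleted replicate 2 and to 1807 without negative control replicate 2. ITGB1 kept its direction throughout. Its log2 fold change of 0.926 no longer passed without the filter (limma adjusted p = 0.142), without the variance trend (0.106) or with the replicate block (0.06), and it ranged from 0.471 to 1.38 with 1 library left out. It was 1.62 (0.00176) with the coding-length trend removed. EEF1A1 ranged from -1.12 to 0.463 with 1 library left out, passing downward without depleted replicate 1 and reversing without depleted replicate 2, and the cause was not tested. FBXO32 stayed lower and not past the threshold under every alternative run. Of 29 lists 9 passed camera, and 0 passed with an estimated correlation (0 at an unadjusted p under 0.05) or with fry (2 at an unadjusted p under 0.05, lowest adjusted p 0.284). At the preset correlation the same 9 passed with median-ratio scaling, without the filter on low values and with the replicate block. With the coding-length trend removed 12 passed, but focal adhesion and nuclear-encoded oxidative phosphorylation genes no longer did. Elongation factors reversed without a call under median-ratio scaling (camera adjusted p = 0.988) and without negative control replicate 2 (0.9) or depleted replicate 2 (0.566), with a range of 0.548 to 0.9 with 1 library left out, and the cause was not tested, and ribosomal proteins reversed to a downward call with the coding-length trend removed (0.00339). For the genes named by rule, without FBXO32, ITGB1 and EEF1A1, 137 of 1138 values under the alternatives lost their call, 8 gained one and 0 reversed. With the replicate block 2419 genes changed. Gene by gene, the same-numbered libraries did not deviate together (correlation of deviations -0.0488). This cannot exclude a shared preparation, since the difference of replicate 2 minus 1 fell with coding length in both groups. Its log2 change per doubling of length was -0.178 in the controls and -0.119 in the depleted libraries. The count-based alternatives (limma-voom and the count model) were not run because the table holds no counts, and scaling by library size alone is what TPM already is. Depth is unknown, so which low values are limited by it cannot be stated.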

Other observations

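The tests on coding length against replicate differences and purine content, on recovery between replicates, on the interferon list after length removal and on N-terminal hydropathy were chosen only after the result was seen. The genes in the next paragraph were chosen after their values were seen.

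B2M and HLA-C, genes of MHC class I antigen presentation, were higher in the depleted libraries. B2M, the light chain of MHC class I, rose from 3536 ± 882 to 9109 ± 1621 TPM (SD, n = 2, limma adjusted p = 0.00043) and HLA-C from 55.4 ± 4.45 to 178.4 ± 18.2 TPM (limma adjusted p = 0.000338). HLA-B (log2 fold change 0.59 ± 0.45) did not pass. S100A10, the annexin A2 partner, rose from 3247 ± 583 to 8413 ± 1698 TPM. NCL, nucleolin, fell from 3125 ± 619 to 260.2 ± 41.7 TPM, and the paraspeckle proteins SFPQ and NONO had log2 fold changes of -3.57 ± 0.37 and -3.13 ± 0.37. These falls passed with the coding-length trend removed (limma adjusted p = 6.32e-09, 1.3e-07 and 2.04e-08).

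Genes with longer coding sequences were lower in the depleted libraries, with a log2 change of -0.41 per doubling of length. The tables argue against low values and the pseudocount, since Spearman's correlation was -0.554 among 2748 genes with a mean of at least 50 TPM, and against purine content as the whole of it, since the partial rank correlation was -0.49 with the purine share held fixed. A library-to-library trend is consistent with the correlation of -0.345 between the 2 negative controls and of -0.215 between the 2 depleted libraries. The change per doubling between groups was 2.29 times the larger one between replicates, too little, with 2 libraries per group, to tell a part due to FBXO32 depletion from such a trend.

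Of the 13 mitochondrially encoded genes, 12 fell, with a list median of -3.13. The coding-length trend is argued against as the cause, since their list's median log2 fold change was -3.16 after its removal. A difference in recovery of mitochondrial ribosome footprints between preparations stays open. The summed mitochondrial TPM differed 4.94-fold between groups and up to 1.91-fold between replicates, a ratio of 0.405 on the log2 scale, and a change in mitochondrial translation or mRNA after depletion was not tested and stays open too.

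The interferon-stimulated genes are not accounted for by coding length, since the list passed camera with the trend removed (adjusted p = 3.03e-06), nor by IFI6 alone, since it passed without it (adjusted p = 0.000305). Both tests used camera's preset correlation. With an estimated one, which 4 libraries determine poorly, no list passed, this one included (camera adjusted p = 0.927). The labels do not say how depletion was achieved or whether control cells went through the same steps, so an effect of FBXO32 loss and one of the procedure or of a selected population stay open and were not tested.

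A hypothesis is that products entering the secretory pathway gained footprints relative to others. Genes whose first 40 residues hold a stretch of 12 with a mean hydropathy of at least 2 (1563 genes) had a length-corrected median log2 fold change 0.683 higher than the 9783 others, and 27.4% of them rose against 6.48%. The same difference was 0.202 between the controls and 0.396 between the depleted libraries, against 0.683 between groups, so a trend between preparations and an effect of depletion cannot be told apart here.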
